A study of Homo sapiens with 4 samples.

How the data were processed

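ChIP-seq was carried out in HepG2 cells with antibodies against ASPM and FoxM1, with 1 ChIP library and 1 control library per antibody (4 libraries). The controls are titled as input, while their antibody field, per the labels, names IgG, so which of these they are is unsettled. Per the labels, 50 ng of DNA went into each preparation, and libraries were made with a kit for Illumina sequencing.

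The authors deposited 1 table of annotated peaks per antibody, each made from a ChIP library and its control. MACS2 2.1.1, HOMER 4.10, ChIPseeker 1.5.1 and the genome build hg38 are named in the submitters' processing notes, without their roles or settings. The aligner, the thresholds and the rule for listing a peak are not given in the sources used here. Per the file headers, each row gives a gene, the chromosome, start, end and strand, a peak number, an annotation class, the signed distance to a transcript start and the transcript. The tables hold no reads, fold enrichment, p or q, so the depth per library is unknown, peaks could not be ranked by strength, and intervals cover counting error only.

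The tables were checked as follows. All peaks lay on the assembled chromosomes, and the chromosome summaries cover 1 to 22 and X. Peak numbers run in genome order and reach beyond the rows listed. Adjacent peaks of the same gene had consecutive numbers in 173268 of 173271 pairs in the ASPM list and in 56278 of 56280 pairs in the FoxM1 list, so in all but 3 and 2 pairs peaks of a gene were listed without gaps. Gene symbols were matched to the RefSeq genes of GRCh38.p14 by symbol or older symbol, for 10488 of 10765 ASPM genes and 7626 of 7827 FoxM1 genes. Of the transcripts with a match, 41.6% in the ASPM list and 41.7% in the FoxM1 list had exactly the RefSeq gene's start, so the RefSeq coordinates were used beside those of the tables.

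A promoter peak was a peak whose distance in the table was at most 1000 bp in either direction. That distance is to the start of the listed transcript; of the promoter peaks of coding genes, 26.05% in the ASPM list and 24.9% in the FoxM1 list lay more than 1000 bp from the RefSeq start. Shares are given with exact 95% Clopper-Pearson intervals. Random placement moved each peak within its own gene, from 2000 bp upstream to the gene's end, or onto coding gene bodies of the same chromosome, 100 times each with fixed seeds; this was done in numpy in place of bedtools. Distances of peaks placed within their own gene were to the RefSeq gene's start. Lists overlapped where peaks shared at least 1 bp. Genes with promoter peaks in both lists were set beside the number that independent lists share among 20037 coding genes. The number of members of each of 10 gene lists with a promoter peak was set beside 10000 random lists matched on gene length in 10 classes. The lists, fixed before the data were examined, were G2/M genes, G1/S and replication genes, spindle pole, centrosome and microcephaly genes, Wnt pathway, hepatocyte, ribosomal protein, neuronal and muscle, blood cell, forkhead and liver cancer driver genes. Density was counted per Mb of the union of coding gene bodies, per chromosome and in 5 Mb bins with at least 0.5 Mb of coding gene bodies.

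The genes to be named were fixed by a rule before the data were examined: ASPM and FOXM1; the 10 strongest peaks of each list; the 10 coding genes of each list with the strongest promoter peak; the 10 coding genes with the strongest promoter peaks in both lists; and up to 4 members of each gene list. The rule ranked by fold enrichment, which the tables lack, so peak width took its place, and this was chosen after the columns were seen. Genes named for their number of peaks, and the gene families of the closing section, were chosen after their values were seen.

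Alternatives planned in advance were every sequence, the list without its widest 1% of peaks, peaks within 1000 bp merged, promoter windows of 500 and 3000 bp, random lists without matching, overlap by 50% of each peak or by midpoints within 200 bp, placement within classes of distance to a transcript start, the share of ASPM peaks in the overlap, and a narrower window at the ASPM and FOXM1 genes. Alternatives added after the data were seen were peaks wider than the median, a random draw of as many ASPM peaks as FoxM1 peaks, placement within the own gene, a 10 kb shift, and lists matched on chromosome and length. Settings by fold enrichment or q, and the forkhead motif at peak summits, which needs peak summits or a genome sequence, were not analysed here.

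The steps were tested on simulated data with known answers. Simulated ASPM peaks depleted at promoters to a ratio of 0.407 gave 0.446, a slight understatement of the depletion. These peaks were simulated over RefSeq genes and measured to RefSeq starts, unlike the listed peaks, whose distances are to the listed transcript's start. The direction of any bias in the real lists therefore does not follow from this simulation. A planted overlap of 20% of simulated FoxM1 peaks was recovered as 19.8%, and lists without planted overlap gave 0.0162%. Among 200 simulated gene lists without enrichment at ASPM promoter peaks, 2% lay in the upper 5% of random lists, and 85% did when genes with a promoter peak were drawn with a weight of 3. The simulated share of genes with a promoter peak was not matched to the 5.97% of the ASPM list. Gene lists at FoxM1 promoter peaks, which 2.09% of genes had, were not simulated. The 85% is therefore not the power for the lists below. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.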

Results

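Chromatin immunoprecipitation with sequencing was carried out in HepG2, a human hepatocellular carcinoma cell line, with an antibody against ASPM, a spindle pole protein mutated in primary microcephaly, and with an antibody against FoxM1, a forkhead transcription factor that drives genes of the G2 and M phases. Each antibody had 1 ChIP library and 1 control library, 4 libraries in all, so no value has a replicate check and no test between conditions was possible. The ASPM list held 184037 peaks assigned to 10765 genes, and the FoxM1 list held 64107 peaks assigned to 7827 genes. The lists carry no reads or peak scores, so the depth of the libraries is unknown, and the confidence intervals below cover counting error only. Median peak width was 202 bp in the ASPM list and 199 bp in the FoxM1 list. In both lists the narrowest width was 158 bp, shared by 36.7% of ASPM peaks and 35.1% of FoxM1 peaks. Introns held 93.1% of ASPM peaks and 93.3% of FoxM1 peaks, and exons held 4.37% and 4.19%. The annotation's own promoter class held 1.94% and 1.90%, and its transcript end class 0.592% and 0.599%. No listed peak had another class, such as intergenic, so these are shares of peaks listed at genes and not of all numbered peaks. The peak numbers reached 437186 and 159281, so 42.1% and 40.2% of the numbered peaks are in the lists, and the values below describe the listed peaks.

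The series asks whether ASPM and FoxM1 regulate each other, which the lists address through the peaks at the 2 genes. At the ASPM gene on chromosome 1 (197084127 to 197146669, hg38), the FoxM1 list held 9 peaks, 7 in introns and 2 in exons. The FoxM1 peak nearest to the transcript start lay in exon 3 of 28, 4095 bp downstream (197142461 to 197142688, 227 bp wide), and no FoxM1 peak was listed at the ASPM promoter. The peak numbers run on without a gap from that exon 3 peak to the next one in ZBTB41 at 197153968, so 0 unlisted FoxM1 peaks fall in the 11.3 kb around the ASPM start. At the FOXM1 gene on chromosome 12 (2857680 to 2877174), neither list held a peak in the gene or within 10 kb of it. In the ASPM list the nearest peaks were in CACNA1C, a calcium channel gene, and in TULP3, and 11 unlisted peak numbers fall in the 214 kb between them, which includes FOXM1. In the FoxM1 list 5 unlisted numbers fall in the 812 kb between peaks of CACNA1C and PRMT8, so unlisted peaks at FOXM1 are not excluded for either antibody.

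Peaks of the ASPM antibody at the ASPM gene itself numbered 15, of which 9 were in exons and 6 in introns. The large exon 18 held 5 of them, the widest of 555 bp at 197102338 to 197102893. Around the ASPM start, 3 unlisted ASPM peak numbers fall in the 11.8 kb between listed peaks. None of the 9 FoxM1 peaks in the gene overlapped an ASPM peak, and the closest midpoints were 227 bp apart. The density at the gene was near that of its surroundings. The 5 Mb bin that holds ASPM, from 195 to 200 Mb, had 294.7 ASPM peaks and 117 FoxM1 peaks per Mb of coding gene bodies. The gene itself had 239.8 and 143.9 per Mb, and at the rate of the bin it would hold 18.4 and 7.32 peaks. At the rate of its own bin, the 19.5 kb FOXM1 gene would hold 2.25 ASPM peaks and 0.676 FoxM1 peaks, against the 0 listed.

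**Figure D1:**
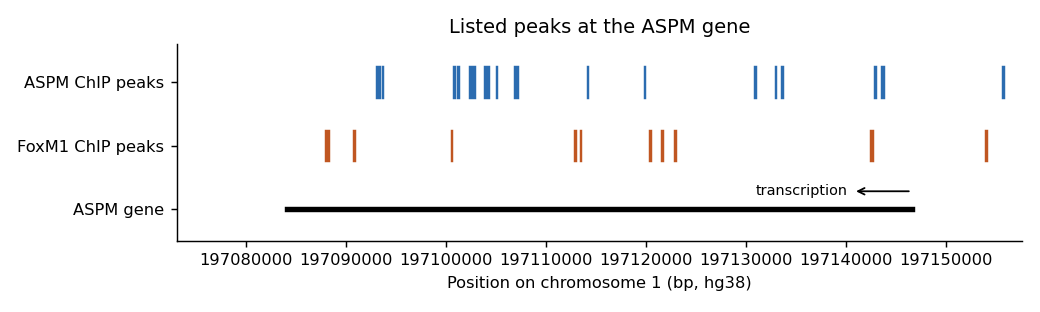
Listed peaks at the ASPM gene, with position on chromosome 1 (bp, hg38) on the horizontal axis; blue blocks are ASPM ChIP peaks, orange blocks FoxM1 ChIP peaks and the black bar the gene, transcribed from right to left. Both lists have peaks along the gene body, the nearest FoxM1 peak to the start lies 4095 bp downstream, and the rightmost block in each row belongs to ZBTB41.

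Promoters were the second question, since a transcription factor such as FoxM1 is usually mapped to them. Within 1000 bp of a transcript start, the widest ASPM peaks were at C6, a complement component (947 bp), at the membrane protein gene MS4A6E (929 bp), and at the olfactory receptor genes OR2T2 (919 bp), OR2A7 (843 bp) and OR4C3 (793 bp). Others were at the peptide transporter gene SLC15A2 (794 bp), FNDC7 (772 bp), the glycosyltransferase C1GALT1 (760 bp), TCHHL1 (750 bp) and WDR64 (743 bp). In the FoxM1 list the widest were at the hyaluronidase family gene HYAL4 (1021 bp), TRIM49C (984 bp), the olfactory receptor genes OR4F17 (741 bp), OR2A25 (719 bp) and OR4F5 (603 bp), the peroxisomal transporter ABCD2 (705 bp), the bitter taste receptor TAS2R39 (668 bp), the cytokine IL36G (601 bp), the cytochrome P450 gene CYP3A43 (600 bp) and TEP1 (579 bp). Starts are those of the transcript listed with each peak: the peaks at C6, MS4A6E, HYAL4 and TEP1 lie 48.8, 7.25, 65.5 and 41.4 kb inside the RefSeq gene, and that at IL36G lies 5.35 kb upstream of it. TRIM49C and the olfactory receptor genes have close paralogs, between which reads can be misplaced. Width was ranked in place of the fold enrichment, which the lists do not carry.

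Promoter peaks were a small share of each list. They numbered 1433 in the ASPM list, 0.779% (95% Clopper-Pearson interval 0.739 to 0.820%), and 480 in the FoxM1 list, 0.749% (0.683 to 0.819%), and the intervals of the lists overlap. Placing each peak at random within its own gene put 2.19% of ASPM peaks and 2.23% of FoxM1 peaks there, so the observed shares among genes with a RefSeq match were 0.357 and 0.336 times those of random placement. The observed distances are to the listed transcript's start and the random ones to the RefSeq gene's start, so the ratios compare unlike starts. They also compare unlike spans where listed transcripts reach beyond the RefSeq gene, since random placement kept to the RefSeq span. In the ASPM list the lowest ratio, 0.263, was in the 500 bp upstream of the start, and the FoxM1 list had 0.238 in the same interval. The ratio stayed near 0.7 in the ASPM list and 0.6 in the FoxM1 list from 2000 to 4500 bp downstream and passed 1 beyond 5500 bp. With a window of 3000 bp the shares were 2.61% and 2.501%, again below random placement at 5.31% and 5.37%.

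**Figure D2:**
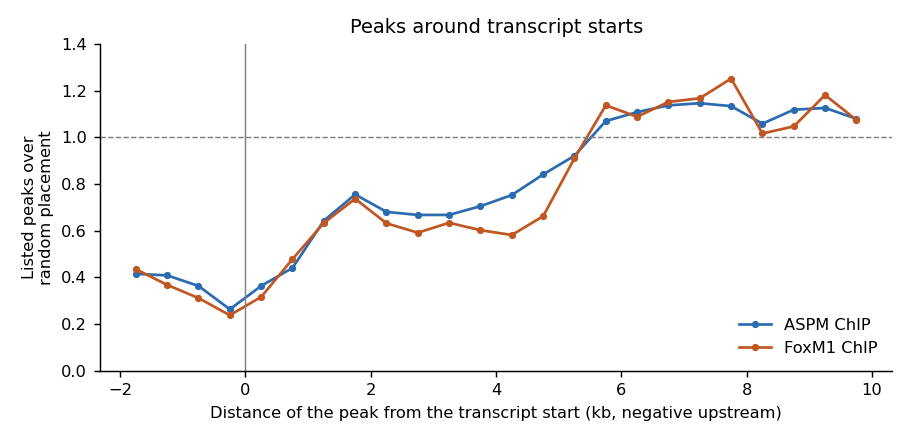
Listed peaks around transcript starts, with the distance from the start (kb, negative upstream) on the horizontal axis and the number of listed peaks over the mean of 100 random placements within the same genes on the vertical axis; blue points are the ASPM list and orange points the FoxM1 list, in bins of 500 bp. Both lists lie below 1 up to 5 kb from the start, with their lowest values of 0.263 and 0.238 just upstream of it. Listed peaks are placed by the listed transcript's start and random ones by the RefSeq gene's start.

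Among the gene lists fixed in advance, the G2/M genes, which include the textbook targets of FoxM1, had no listed FoxM1 peak at a promoter. The count was 0 of 50, where random lists matched on gene length had 0.986 on average and 36.7% of them also had 0. CCNB1, PLK1, AURKB, CDC25B, BIRC5 and CENPA had no listed FoxM1 peak anywhere in the gene, while 20 of the 50 genes had at least 1, against 18.1 in random lists. Of the 30 G2/M genes without a listed FoxM1 peak, 13 had no unlisted number between the flanking listed peaks. At the others unlisted FoxM1 peaks are not excluded. The most FoxM1 peaks within a G2/M gene were 12 each in the mitotic kinesin KIF14 and the cytokinesis factor ANLN, with 9 in the centromere protein gene CENPF, 8 in the spindle checkpoint kinase BUB1 and 8 in CDK1. The FoxM1 list reached a promoter in 4 of the 394 distinct list genes. These were HBB among the blood cell genes, NRAS among the liver cancer drivers, and STMN2 and GAP43 among the neuronal and muscle genes. The HBB peak lies 3.26 kb upstream of the RefSeq start of HBB and counts by the start of the listed transcript. By the RefSeq starts the blood cell count is 0 and the neuronal and muscle count 3, with GRIA1 added. G1/S and replication, spindle pole, Wnt, hepatocyte, ribosomal protein and forkhead genes had 0 promoters with a FoxM1 peak, of 40, 30, 44, 42, 47 and 36 genes. None of the 10 lists lay in the upper 2.5% of random lists. The low side could not be reached, since a count of 0 was met in 36.7% to 53.6% of random lists. With a promoter window of 3000 bp, 1 list lay in the upper 2.5%, the blood cell genes with 6 of 38 against 2.20 in random lists.

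For ASPM, the list of spindle pole, centrosome and microcephaly genes, to which ASPM belongs, had promoter peaks at 3 of 30 genes, the katanin subunit KATNA1, the centriole protein CEP152 and the dynactin subunit DCTN1, against 1.80 in random lists. The CEP152 peaks lie at an internal transcript start, 70.02 and 69.6 kb inside the RefSeq gene, and by the RefSeq start the count is 2. The G2/M genes had 1 of 50, a peak of the minimum width 698 bp downstream of the start of the mitotic kinase NEK2, against 2.77 in random lists. Hepatocyte genes had 2 of 42 (A1CF and the fibrinogen gene FGG), blood cell genes 3 of 38 (CD2, CD3G and BTK, the last at a transcript start 5.47 kb inside the RefSeq gene), neuronal and muscle genes 3 of 44 (GAP43, MYH2 and MYH4), ribosomal protein genes 1 of 47 (RPS20) and liver cancer drivers 1 of 36 (NRAS). By the RefSeq start the blood cell count stays 3, with HBB in place of BTK. G1/S, Wnt and forkhead genes had 0 of 40, 44 and 36. In total 14 of the 394 genes had an ASPM promoter peak, and 0 of the 10 lists lay in the upper 2.5% of random lists. The low side could not be reached by the lists with a count of 0, which 7.90% to 10.6% of random lists also had. With 3000 bp, 2 lists lay in the lower 2.5%, the G1/S genes with 1 of 40 against 6.02 and the Wnt genes with 2 of 44 against 7.07.

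Counted over whole genes, some lists moved further from random. This count was not planned in advance, and the 3 lists described lay furthest from length-matched random lists for ASPM. Liver cancer drivers came next, with 17 of 36 against 22.2, and 3.06% of random lists had as few. ASPM peaks lay in 34 of 50 G2/M genes, against 26.7 in random lists of like length, and 1.65% of random lists had as many. The ASPM list had 20 peaks in KIF14, 19 in CENPF, 16 in ECT2 and 15 in ANLN. Forkhead genes were lower, with ASPM peaks in 8 of 36 against 14.9, and 0.15% of random lists had as few. Those with most peaks were the long genes FOXP2 (182 ASPM peaks), FOXN3 (60) and FOXP1 (51). Wnt pathway genes had ASPM peaks in 18 of 44 against 25.1, and 0.67% of random lists had as few. Among them the kinase gene GSK3B held 102 and the R-spondin receptor gene LGR4 held 66. Both lie in dense 5 Mb bins, of 540.1 and 568.7 ASPM peaks per Mb. Peak numbers per gene in this comparison are not adjusted for gene length or region. Without matching on gene length, 1.61%, 0.03% and 9.63% of random lists were as extreme for the G2/M, forkhead and Wnt genes, so the low count of the Wnt genes depends on the matching. In the FoxM1 list the same 3 counts were 20, 7 and 15, against 18.1, 10.9 and 18.8. These percentiles describe these lists and are not tests over replicates. Of the 28 forkhead and 26 Wnt genes without a listed ASPM peak, 4 and 2 had no unlisted number between the flanking listed peaks. At the others unlisted ASPM peaks are not excluded.

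The lists were then compared with each other. Of the FoxM1 peaks, 13791 overlapped an ASPM peak by 1 bp or more, 21.5% (21.2 to 21.8%), which is 7.49% of the ASPM peaks. Random placement on coding gene bodies of the same chromosome gave 8.47%, so the observed overlap was 2.54 times as high. Placement within each peak's own gene gave 14.1%, and against it the ratio was 1.52. Moving the FoxM1 peaks by 250 bp lowered the overlap to 19.3%, by 1 kb to 16.2%, by 10 kb to 14.2% and by 100 kb to 9.48%. Shared FoxM1 peaks had a median width of 231 bp against 191 bp for the others, and 1.02% of them (0.855 to 1.197%) lay at promoters against 0.676% (0.606 to 0.751%). Wider peaks share 1 bp more readily, so the width difference can follow from the way overlap is counted.

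**Figure D3:**
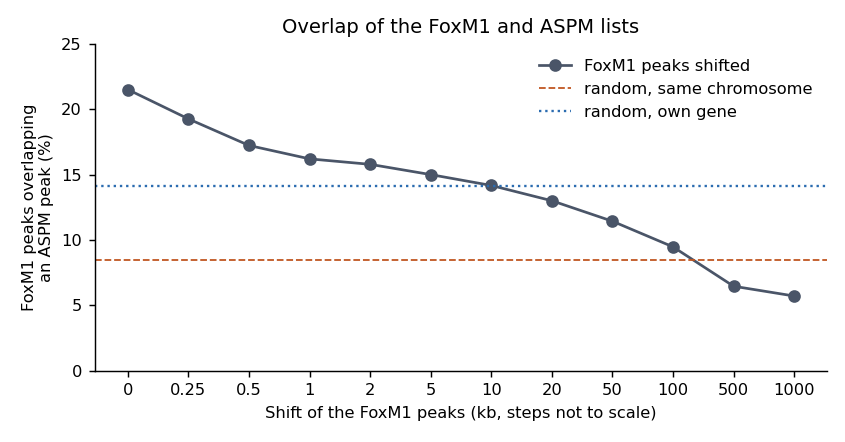
Percent of FoxM1 peaks that overlap an ASPM peak, on the vertical axis, after a shift of the FoxM1 peaks by the distance on the horizontal axis (kb, mean of both directions, steps not to scale); the dashed line is random placement on the same chromosome and the dotted line random placement within the own gene. The overlap falls from 21.5% without a shift to 14.2% at 10 kb and 5.72% at 1000 kb.

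Genes with a promoter peak in both lists included TRIM49C, the protease inhibitor genes SPINK13 and SPINT4, the semenogelin gene SEMG2, the skin barrier genes SPRR2D and FLG2, the beta-defensin gene DEFB116, the lymphocyte receptor gene SLAMF6, the sensory neuron receptor gene MRGPRX1 and PPIAL4F, a member of a family of near-identical copies. In TRIM49C the ASPM peak of 512 bp (90031662 to 90032174 on chromosome 11) lay inside the FoxM1 peak of 984 bp. In DEFB116 the peaks of the lists lay on either side of the start, at -156 and 742 bp. By the RefSeq starts, the ASPM peaks of SPRR2D and SPINK13 lay at -1580 and -1003 bp, outside the 1000 bp window. Of 20037 coding genes, 1196 had an ASPM promoter peak and 418 a FoxM1 promoter peak, and 197 had both, where independent lists would share 24.95. Within classes of chromosome and gene length 34.0 would be shared, and the widest promoter peaks overlapped in 82 of the 197 genes. For peaks anywhere in the gene, 7297 genes were in both lists against 3961 for independent lists, 96.0% of the FoxM1 genes.

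The widest peaks of all lay within genes. In the ASPM list they were in MARCHF11 (2060 bp, intron 2), the aminotransferase gene AGXT2 (1851 bp), BBOX1 of carnitine synthesis (1779 bp), the noncoding gene LINC02218 (1716 bp), AL117339.4 (1679 bp), ANO3 (1642 bp), the anion transporter SLCO3A1 (1633 bp), METTL15 (1612 bp), NUP210L (1572 bp) and the growth hormone receptor gene GHR (1542 bp). The FoxM1 list had its widest peaks in the dynein chain gene DYNC1I1 (1471 bp), the transcription factor gene MEF2A (1434 bp), NBPF11 (1352 bp, exon 16), ZDHHC11B (1312 bp), RGPD5 (1283 bp), the topoisomerase gene TOP1 (1250 bp, exon 4), FAM13C (1179 bp), GARNL3 (1178 bp), ANO3 (1151 bp) and LGR4 (1146 bp). NBPF11, ZDHHC11B and RGPD5 belong to families of near-identical copies. MARCHF11, AGXT2, LINC02218 and GHR lie on the short arm of chromosome 5, and BBOX1, ANO3, METTL15 and LGR4 lie together on chromosome 11.

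Peak density differed several-fold between chromosomes in both lists. Chromosome 7 had 279.3 ASPM and 118 FoxM1 peaks per Mb of coding gene bodies, chromosome 5 had 246.5 and 105, and chromosome 1 had 206 and 81.2. The lowest in the ASPM list were chromosomes 19, 22 and 4 with 46.5, 50.7 and 51.1, against 145.7 genome-wide. In the FoxM1 list they were chromosomes 4, 18 and 21 with 7.69, 9.34 and 11.1, against 50.7 genome-wide. Within chromosomes the density changed in steps at the same places in both lists. On chromosome 5 the bins from 5 to 45 Mb held 379.7 to 597.5 ASPM peaks per Mb, and those from 50 to 70 Mb held 178 to 187.5. On chromosome 3 the bins from 55 to 90 Mb held 40.3 to 66.4 ASPM peaks per Mb, and the bin from 115 to 120 Mb held 540.1.

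**Figure D4:**
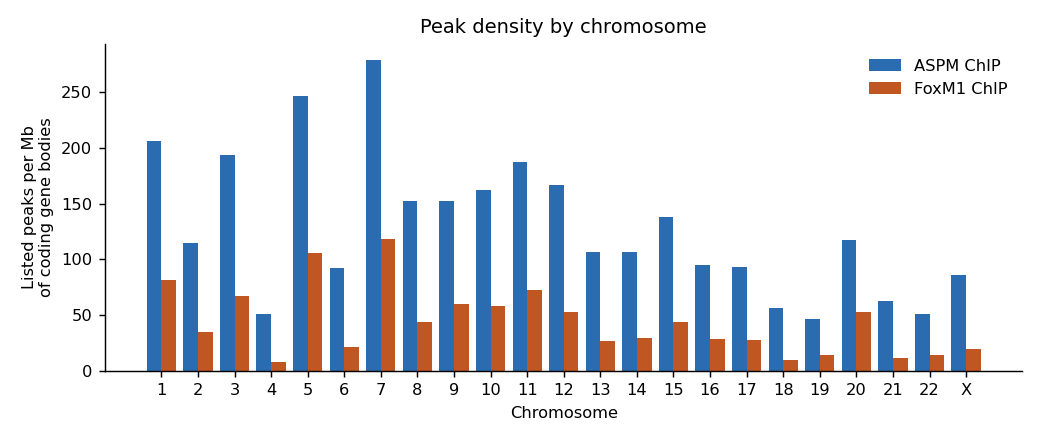
Listed peaks per Mb of coding gene bodies (vertical axis, from 0) on chromosomes 1 to 22 and X (horizontal axis); blue bars are the ASPM list and orange bars the FoxM1 list, 1 ChIP library each. Chromosomes 7, 5 and 1 are the densest in both lists, at 279.3, 246.5 and 206 ASPM peaks per Mb.

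**Figure D5:**
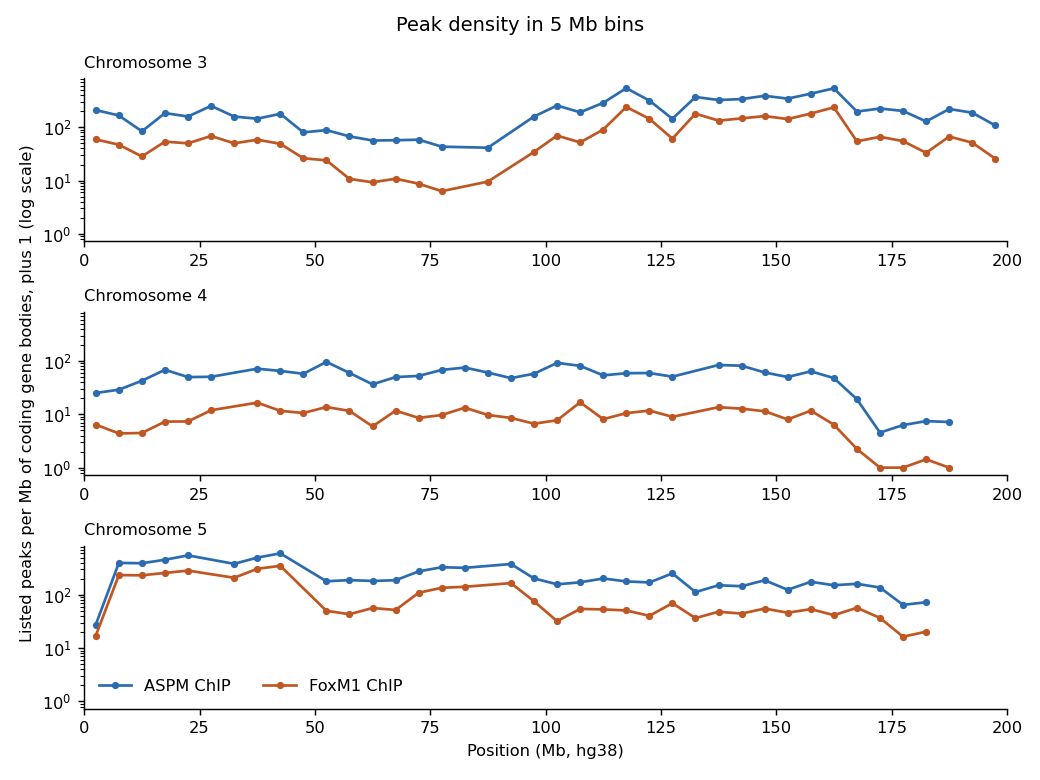
Listed peaks per Mb of coding gene bodies plus 1 (log axis) in 5 Mb bins along chromosomes 3, 4 and 5 (horizontal axis, Mb); blue points are the ASPM list and orange points the FoxM1 list. The lists rise and fall at the same positions, and chromosome 5 drops after 45 Mb from 597.5 to 178 ASPM peaks per Mb.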

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

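The peak numbers in the lists point to peaks that no row describes. In the ASPM list 253149 numbers up to the highest have no listed peak, and in the FoxM1 list 95174 have none. The peaks behind these numbers are outside the lists compared in the report, and what they are is not given in the sources used here. With 1 library per group, no difference between groups and no outlying sample was looked for.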

How the results depend on the processing

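Of 60 comparisons of a result with its value under another setting, several for the same result, 11 could not change by construction. Of the other 49, 25 stayed within 1.5 times (counts and ratios) or the 95% interval (shares), and 24 moved. Only the ratio of the overlap to random placement could be scored as reversed, and 0 of its settings were. Counts and shares had no such score. Peaks wider than the median, a random draw of ASPM peaks, placement within the own gene, a 10 kb shift, or matching on chromosome were chosen after seeing the data. Wider windows hold more peaks by construction: at 3000 bp from a start the promoter shares were 2.61% (ASPM) and 2.501% (FoxM1), 796 genes were in both lists, 42 and 15 list genes had a promoter peak, and 2 and 1 gene lists lay in the outer 2.5%; at 500 bp the shares were 0.342% and 0.307% with 78 shared genes. Peaks wider than the median, fewer by construction, numbered 91991 (ASPM) and 31849 (FoxM1), with an overlap of 17.6%, 78 shared promoter genes, 8 list genes with an ASPM promoter peak and 4 FoxM1 peaks around ASPM. The overlap was 20.2% without the widest 1%, 7.33% with 50% of each peak shared, 17.5% by midpoints, 7.49% as a share of ASPM peaks and 7.64% with as many ASPM as FoxM1 peaks, which left 69 shared promoter genes. Against random placement it was 1.52 within the own gene and 1.52 against the 10 kb shift, and 2.48 to 2.95 under the other settings. Settings by fold enrichment or q, the equal-sized list by q, and all motif settings were not run. No paired analysis was possible because each group has 1 library and no result comes from a test. The unknown depth limits what the absence of a peak means.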

Other observations

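Promoter peaks were counted in 13 gene families, sorted by symbol after the data were seen. Olfactory receptor genes had an ASPM promoter peak in 124 of 392 members and a FoxM1 promoter peak in 57, against 35.5 and 14.4 in random lists matched on chromosome and gene length. The epidermal genes of the cornified envelope on chromosome 1 had 22 and 11 of 38, against 4.56 and 2.16, with peaks at FLG, SPRR2E, SPRR2D and TCHHL1 in the ASPM list and at FLG2, SPRR2D, RPTN and LCE6A in the FoxM1 list. Beta-defensin genes had 14 and 10 of 39, against 2.99 and 1.44, bitter taste receptor genes 7 and 2 of 25, against 2.05 and 0.842, and TRIM genes 12 and 5 of 77, against 5.48 and 2.18. Keratin-associated protein genes, also expressed in few tissues, had 9 and 1 of 94, against 6.72 and 1.43. Among broadly expressed genes, proteasome subunits had 4 and 0 of 40, against 2.13 and 0.694. Genes with an EIF symbol, translation initiation factors but also kinase genes such as EIF2AK4, had 3 and 1 of 56, against 3.16 and 1.16. Mitochondrial complex I genes had 1 and 0 of 46, against 2.68 and 0.934, and replication-dependent histone genes had 3 and 1 of 84, against 5.40 and 1.59. Zinc finger genes with a ZNF symbol, at 25 and 8 of 517 against 20.96 and 7.14, and solute carrier genes, at 25 and 9 of 386 against 23.3 and 8.03, lay near random lists. Of 56 cytochrome P450 genes, 2 had an ASPM and 5 a FoxM1 promoter peak, against 3.09 and 1.12, with CYP3A43, CYP3A5, CYP7B1 and CYP2C8 among the latter. Many members of these families have close paralogs, so reads can be misplaced between copies.

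The genes with most peaks were long. CNTNAP2, of 2304 kb, held 733 ASPM and 280 FoxM1 peaks, DLG2 held 717 ASPM peaks, CTNNA3 623 and the cadherin genes CDH12 and CDH18 606 and 562, and the FoxM1 list had most peaks in the phosphatase gene PTPRT (310). Some shorter genes held more peaks in both lists than the rate of their own 10 Mb region gives over their RefSeq length. Peaks were counted by the gene named in the lists. Where listed transcripts reach beyond the RefSeq gene, an excess can follow from the longer span, which was not checked. TTC33 on chromosome 5 held 139 ASPM peaks where the regional rate gives 24.6, and 82 FoxM1 peaks where it gives 14. The dioxin receptor gene AHR held 94 and 34 against 16.7 and 6.65, the fatty acid translocase gene CD36 138 and 53 against 28.5 and 11.5, and the retinaldehyde dehydrogenase genes ALDH1A2 and ALDH1A1 115 and 28 against 20.1 and 5.60, and 81 and 41 against 21.3 and 8.83. Across 8353 genes the departures from the regional rate went together in the lists (Pearson r 0.62, Spearman rho 0.54), with genes not being independent replicates. The same RefSeq lengths were used for both lists, so a span that differs from the listed transcripts moves a gene alike in both. How much of the correlation follows from that was not checked.

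In the 3 patterns that follow, the tests of active genes near starts, of the HepG2 copy gains and of overlap in neuronal, muscle and blood cell genes were set before their results were seen, and the other tests after. The first pattern is the lack of peaks near transcript starts. In the downstream ratios below, observed distances are to the listed transcript's start and random ones to the RefSeq gene's start. Peaks left out of the lists do not account for it: at 168 ASPM and 43 FoxM1 head-to-head gene pairs with listed peaks of both genes near their starts, the unlisted numbers came to at most 1.29% of the missing peaks; a first version over all pairs gave 316.4% and 260.5%, with all 413 and 99 unlisted numbers in the 79 and 58 pairs where a listed transcript starts more than 1000 bp from the RefSeq start, and 0 in the other 309 and 177. A pile-up of control reads at starts, which MACS2's default local background of 10000 bp would carry 5000 bp to each side, stays open: the density at 5500 to 7500 bp over that at 2500 to 4500 bp was 1.59 times random placement in the ASPM list (1.51 to 1.68) and 1.90 in the FoxM1 list (1.73 to 2.08), but these intervals were chosen from the profile that showed the step, so the ratio does not support that explanation. Upstream of starts, looked at afterwards, the same ratio was 1.37 (1.24 to 1.52) in the ASPM list and 1.78 (1.47 to 2.17) in the FoxM1 list, but 1.149 (0.922 to 1.43) and 1.374 (0.918 to 2.07) at starts with no end of another coding gene within 10000 bp, so neighbouring starts cannot be set aside. Whether active genes carry this more could not be told: the lists of broadly active genes against those of neuronal, muscle and blood cell genes had 1.31 (0.659 to 2.65) against 1.66 (0.726 to 4.02) in the ASPM list and 2.22 (0.956 to 5.56) against 1.25 (0.269 to 6.3) in the FoxM1 list, with too few peaks to decide; base composition was not tested, nor was a biological explanation.

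The second pattern is the stepwise change of density along chromosomes in both lists. The authors' listing does not account for the difference between chromosomes 5 and 4. Chromosome 5 used 5.50 times as many ASPM peak numbers as chromosome 4, listed or not, and 15.3 times as many FoxM1 numbers. Gene density does not account for that difference as the whole cause, since bins with 10 to 40 coding genes still had 3.43 times the median ASPM density on chromosome 5 as on chromosome 4. The chromosomes usually described as gained in HepG2 (2, 14, 16, 17 and 20) were not denser after a fit on gene density, with a median log2 residual of -0.12 in the ASPM list and -0.04 in the FoxM1 list against 0.38 and 0.50 elsewhere. These comparisons are all between whole chromosomes, so none of them can test the steps within chromosomes. On chromosome 2 the bin from 120 to 125 Mb held 288.1 ASPM peaks per Mb and that from 130 to 135 Mb 55.9. The copy number of the cells used and the reads of the controls were not analysed here, and no biological explanation was tested.

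The third pattern is the overlap of the lists beyond random placement. Shared differences between genes in density do not account for all of it, since the highest of 100 placements within the own gene reached 67.3% of the observed overlap. A common background of both libraries, independent of the antibody, cannot be told apart from binding of both proteins at the same sites: the overlap over own-gene placement was 1.296 (0.905 to 1.78) in neuronal, muscle and blood cell genes and 1.52 (1.499 to 1.544) in all coding genes, and the 229 FoxM1 peaks of those lists are too few to decide. Binding of ASPM and FoxM1 at shared sites stays open as the biological explanation and was not tested.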
